A study of Homo sapiens with 460 samples.

How the data were processed

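Single-cell RNA-seq values of 460 cells were used: 213 unsorted H1 cells (passages 30 to 35) and 247 sorted H1-Fucci cells (passages 35 to 40), grown in E8 medium on Matrigel, per the labels. Cells were captured on chips for cells of 10 to 17 µm, amplified with SMARTer chemistry, made into Nextera XT libraries and sequenced, 24 libraries per lane, as single 67-base reads on a HiSeq 2500, per the labels' protocols. The deposited values are a normalized signal: gene-level expected counts that the authors scaled per cell, per the labels. The scaling method is not given in the sources used here. CASAVA 1.8.2, Bowtie 0.12.8, RSEM 1.2.3 and the genome build hg19 are named per the submitters' processing notes, without their roles. Within each cell the values behaved as an expected count with decimals divided by 1 factor: the most frequent value of a cell was taken as its recovered read, and 100% of its values under 50 reads were multiples of 0.01 of that read. A median of 46.5% of the values of a cell were whole multiples of the recovered read at a tolerance of 0.005, so whole reads could not be recovered. The depth of a cell was computed as its total over the recovered read, and ranged from 231015 to 10176181; 6 H1 cells were under 1000000. Amplified reads without molecular identifiers are not independent molecules. The highest correlation between log values of 2 cells was 0.713, so no pair of cells repeated another.

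The table held 19084 genes, named by the symbols of the file, and genes keep those symbols here. No coordinates were used, since the annotation of that build was not used here. The unit of comparison was the capture (3 H1 experiments, 1 capture each for G1, S and G2M), with the mean over its cells of log2(value + 1) as its value. Cells were not treated as replicates. Because the mean is taken of log2 values, a difference on this scale is not the log2 ratio of the mean values given beside it. Phases were compared as differences of capture means with no test, beside the SD and range of the 3 H1 experiments, and list medians with their percentile among 10000 random lists matched on mean expression in 20 bins. Genes with a mean of at least 10 were kept, which left 10758 in H1 and 10771 over the 6 captures.

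In H1 each gene was correlated with the mean standardized log2 value of a list (the gene itself left out) within each experiment, by Spearman correlation with the number of genes detected held. The 3 Fisher-transformed values were tested against 0 with limma 3.58.1 in R 4.3.3 (moderated, trend option, two-sided, Benjamini-Hochberg threshold 0.05). H1-Fucci and H1 were compared with limma on the capture means, 3 against 3. Whether the 3 H1-Fucci captures came from separate cultures is not given in the sources used here. Random gene sets matched on expression were drawn 10000 times for shares and 1000 times for correlations within lists. The paired-sine search was written anew from the published idea. It used genes with a mean of at least 100 and a variance above the fitted line, rescaled between the 5% and 95% quantiles, took the top 5% by best pair, and grouped them by K-medoids (cluster 2.1.8.1) with 2 to 10 groups chosen by silhouette. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Intervals of shares are exact Clopper-Pearson 95% intervals.

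The gene lists, the tests, the rule for named genes and the main alternatives were fixed before the data were examined. Lists were G1/S, G2/M, replication-dependent histones, cyclins and regulators, pluripotency, ectoderm, mesendoderm, definitive endoderm, trophoblast, fibroblast, p53 targets, immediate early, heat shock, glycolysis, cholesterol synthesis and ribosomal proteins. Of 13 mitochondrially encoded genes 0 were matched, and they were not analysed here. Measured members were 43 of 43 for G1/S, 53 of 54 for G2/M, 16 of 29 for histones, 3 of 12 for ectoderm, 1 of 12 for mesendoderm (BMP4), 2 of 10 for definitive endoderm (AFP and KRT19), 1 of 12 for trophoblast (TFAP2C) and 5 of 12 for fibroblast. Named genes were, for each phase difference, up to 10 per direction with the largest difference beyond the range of the H1 experiments and detected in at least 25% of cells of the higher capture, and up to 6 per list. For the largest differences a mean of at least 10 was required in the higher capture only. NUP210L (mean values of 20.4 in G1 and 1.92 in G2M) and HIST1H2BL (2.18 in G1 and 15.3 in S) were named this way and rest on low values. For H1-Fucci against H1 they were up to 12 per direction past the threshold and up to 4 per list. For co-variation they were up to 12 genes outside the list with the largest positive correlation and up to 6 members, and for the sine search the members of a group up to 30. CDT1, GMNN, CCND1, CCNE1, CCNE2, CCNA2, CCNB1, CDK1, POU5F1, NANOG and SOX2 were always named. Genes with negative correlations, CCNB2 and CDC20 in the G2M and G1 comparison, and the sine group with glycolytic genes were named after their values were seen.

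Alternatives were pseudocounts of 0.1 and 10, cells rescaled to a total of 1000000, the log2 of the mean value, no filter or a mean of at least 50, 5% of cells left out at each end by genes detected, no adjustment for genes detected, Pearson correlation, no trend in limma, other settings of the sine search, and each capture left out. Added after seeing the data were the omission of the 6 cells under 1000000 expected counts and holding the cell number of the title. On simulated data, the comparison of lines over 10771 genes recovered 30% of changes of log2 1 and 66% of log2 2, with 5 other genes called. The co-variation test over 10758 genes recovered 66% of genes set at a correlation of 0.3 and 99% at 0.5, with 7 others called. The drift test over 10771 genes recovered 97% at 0.3 and 100% at 0.5, with 12 others. The sine search over 2666 genes placed 60 of 60 set genes among the top genes, with at most 20 in a group. Those set genes followed sine curves with little noise, and every other gene was shuffled over cells, so no other genes varied together. The recovery by the sine search thus does not give its sensitivity in the real cells. The values of 1 list member that the naming rule selected are not reported here.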

Results

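RNA was sequenced from 460 single cells of the human embryonic stem cell line H1. Of these, 213 were unsorted H1 cells from 3 experiments of 62, 78 and 73 cells. The other 247 were H1-Fucci cells, a derivative of H1 with fluorescent reporters of cell cycle phase (in such lines usually built on parts of CDT1 and GMNN), sorted by flow cytometry into G1 (91 cells), S (80 cells) and G2M (76 cells). Each sorted phase came from 1 capture, so differences between phases have no replicate check; the spread of the 3 H1 experiments is given beside them as a yardstick. The expected counts behind a cell ranged from 231015 to 10176181, with medians of 1782663, 3389366 and 5133962 in H1 experiments 1, 2 and 3 and of 4344798, 4066340 and 5170308 in G1, S and G2M. The median number of genes detected was 9974, 10018 and 9722 in the H1 experiments, 9970 in G1, 10588.5 in S and 10590.5 in G2M. The series title names a search for genes that oscillate in unsorted cells, and the sorted cells carry a label of phase to set beside such genes.

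Cells sorted as S differed from cells sorted as G1 in histone and mitotic transcripts. Replication-dependent histones, which package newly made DNA, were higher in S, with 13 of 16 measured members higher and a list median of 1.31 on the log2 scale. The linker histone genes led, with HIST1H1B higher by 4.08 (capture means of log2(value + 1) of 3.18 in G1 and 7.26 in S), HIST1H1E by 3.91, HIST1H1A by 3.79, HIST1H1D by 2.88 and HIST1H1C by 2.62. Mitotic genes were lower in S: 47 of 53 members of the G2/M list were lower, with a median of -0.63. KIF20A, a kinesin of cytokinesis, differed by -2.94 (log2 means of 8.13 in G1 and 5.18 in S), PLK1, a kinase of mitotic entry and exit, by -2.86 (8.37 and 5.51), and CCNB1, the B-type cyclin that drives mitosis, by -1.87 (mean values of 2836 and 860).

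The histone median lay at percentile 100 and the G2/M median at percentile 0.00 among 10000 random lists of the same size and expression. The SD of these list medians over the 3 H1 experiments was 0.39 and 0.22. CDK1, the catalytic partner of CCNB1, was 1 of 6 members that were higher in S, by 2.39 (log2 means of 6.85 in G1 and 9.24 in S), and UBE2C was another (1.18). Further G2/M members lower in S were CDCA3 (-2.25), HMMR (-2.13), CDC20 (-1.77), CKS2 (-1.61) and AURKB (-1.60). Outside the lists, the copine gene CPNE8 (3.65), ANKRD36 (3.2), the insulin receptor adaptor GRB14 (3.04), the calcium channel RYR2 (2.71) and the histone gene HIST1H2BL (2.65) were higher in S. TOB1, an antiproliferative factor, was lower by the log2 value -2.66, DEPDC1 by -2.48, ZNF165 by -2.45, the helix-loop-helix inhibitor ID2 by -2.38, ZNF367 by -2.32, ARV1 by -2.27 and C5orf62 by -2.22. Each of these differences exceeded the range of the 3 H1 experiments, which was 1.32 for HIST1H1B, 0.18 for KIF20A and 0.88 for PLK1. For the genes named for the largest differences the naming rule required this, so it is no check on them. The G1/S list, genes of DNA replication and its licensing, had a median of 0.03 (percentile 84.7) and a mean of -0.04, with 23 of 43 members higher; its median was -0.01 when the log2 was taken of the mean value. TIPIN (-1.46), CDCA7 (-1.23), CCNE2 (-1.18, inside its H1 range of 1.43) and DTL (-1.02) were lower in S and BLM was higher (1.16). Reads of near-identical copies make ANKRD36 and single histone genes uncertain, and most histone transcripts lack a poly(A) tail. The histone median depended on how low values were treated, with 1.97 at a pseudocount of 0.1, 0.70 at a pseudocount of 10 and 0.58 without the filter on low values.

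Cells sorted as G2M, set against G1, were higher in CDK1, in histones and in part of the G2/M list, and lower in most of the G1/S list. CDK1 was higher by 3.59, with log2 means of 6.85 in G1 and 10.44 in G2M. UBE2C, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, was higher by 2.82, HJURP, the chaperone of the centromeric histone, by 2.40, and TOP2A, the topoisomerase that untangles sister chromatids, by 2.1. CCNE2, the E-type cyclin that starts S phase, was lower (-2.04, log2 means of 6.27 and 4.23), as were CCNE1 (-1.33) and the phosphatase gene CDC25A (-1.52). Among replication genes, DTL (-1.64), CDCA7 (-1.50) and UHRF1 (-1.17) were lower in G2M.

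By list, 32 of 43 G1/S members were lower in G2M, with a median of -0.22 (percentile 0.00; SD over the H1 experiments 0.12), and 36 of 53 G2/M members were higher, with a median of 0.23 (percentile 99.98). The histone list had a median of 1.0 (percentile 100), with 13 of 16 members higher and 3 lower. The largest were HIST1H1B at 3.10, HIST1H1E at 2.47, HIST1H4C at 2.33 and HIST1H1A at 2.28. The G2/M genes did not move together: 11 members were higher by at least 1, while 17 were lower in G2M than in G1, among them CCNB2 and CDC20. CCNB1 itself was lower in G2M than in G1 by the log2 value -0.46, against a range of 0.12 over the H1 experiments. Other genes higher in G2M were FAM54A (2.89), CPNE8 (2.82), MPHOSPH9 (2.74), RBM23 (2.73), TSHZ3 (2.69) and FBXO5, an inhibitor of the anaphase-promoting complex (1.91). Lower in G2M were C1orf63 (-2.87), the nucleoporin-like gene NUP210L (-2.53), ZNF367 (-2.27), the chaperone gene DNAJB4 (-2.07), ZNF200 (-1.92), SYNC (-1.87), DCAF4L1 (-1.79), LEAP2 (-1.76) and the insulin receptor substrate IRS2 (-1.74). With the log2 taken of the mean value, the G2/M median was 0.06 and the histone median 0.37. The histone median was 1.56 at a pseudocount of 0.1, 0.42 at a pseudocount of 10 and 0.37 without the filter.

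Between G2M and S, the mitotic genes differed most among the lists with more than 1 measured member. Of 53 G2/M members 52 were higher in G2M, 26 of them by at least 1, with a median of 1.00 (percentile 100). AURKA, the kinase of spindle poles, was higher by 3.3 (log2 means of 5.75 in S and 9.01 in G2M), GAS2L3 by 2.79, CDCA3 by 2.77, the spindle protein gene CKAP2L by 2.76, PLK1 by 2.70 and KIF20A by 2.55. CCNB1 was higher by 1.41, CDK1 by 1.2 (inside its H1 range of 1.5) and WEE1, the kinase that holds CDK1 inactive, by 1.13. Replication genes were lower in G2M, with 35 of 43 G1/S members lower and a median of -0.36 (percentile 0.00), as shown by WDR76 (-1.23), UHRF1 (-1.15), MCM6 (-0.68) and FEN1 (-0.65). Histones were lower in 13 of 16 members, with a median of -0.58 (percentile 0.03).

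Of the 53 G2/M members, 42 exceeded the range of the H1 experiments in this comparison. Genes of other lists exceeded it too: 11 higher and 4 lower of 29 cyclins and regulators. For 18 glycolysis genes the counts were 4 and 3, and for 23 pluripotency genes 2 and 4. The share over all genes was not computed. Outside the lists, LMO3 (2.57), DEPDC1 (2.45), ID2 (2.43) and FAM72A (2.43, a gene with near-identical copies and so uncertain) were higher in G2M. The secretogranin gene SCG2 (-2.25), the imprinted gene PEG3 (-2.04), DTX2 (-1.96), CNKSR2 (-1.96), RAP1GAP2 (-1.85), BRAT1 (-1.71), ANKLE2 (-1.70), ZNF354A (-1.70), C3orf70 (-1.65) and the telomere protein gene ACD (-1.60) were lower. Among always named genes, CCNE1 was lower by the log2 value -1.23 and CCNE2 by -0.87 (inside its H1 range of 1.43), CCNA2 differed by 0.08, CDT1 by -0.26 and GMNN by 0.26, and CCND1 differed by 0.15, or by -0.20 with the log2 of the mean value. The 29 cyclins and regulators had medians of -0.11 for S less G1 (percentile 5.24), -0.11 for G2M less G1 (percentile 0.27) and 0.08 for G2M less S (percentile 52), with members on both sides such as PKMYT1, the inhibitory kinase of CDK1 (1.52 for S less G1). Pluripotency genes had medians of -0.07 (percentile 59.2), -0.00 (percentile 49.8) and 0.04 (percentile 11.9) over 23 members. In the order S less G1, G2M less G1 and G2M less S, POU5F1 differed by 0.42, -0.01 and -0.43 (H1 range 0.18). NANOG differed by 0.33, 0.33 and 0.00 (H1 range 0.31), so neither gene stayed inside its range throughout. SOX2 differed by -0.98, -0.18 and 0.80, each inside its H1 range of 1.00. The median over all genes was 0.17 for S less G1, 0.19 for G2M less G1 and 0.05 for G2M less S, and 0.05, -0.03 and -0.08 with the log2 of the mean value, so differences of that size do not set a list apart. A difference over 1 was seen in 12.6%, 8.13% and 6.07% of the genes, against 6.09% to 11.6% between pairs of H1 experiments.

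**Figure D1:**
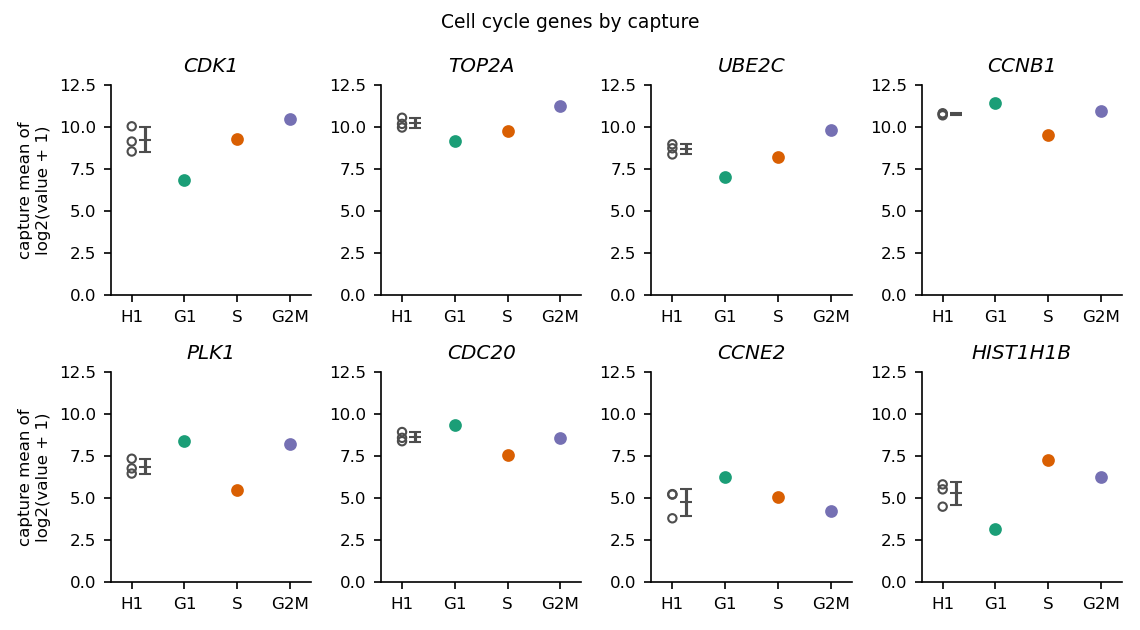
Capture means of log2(value + 1) for 8 cell cycle genes in the 3 unsorted H1 experiments (open circles, with mean and SD beside them) and the 3 sorted H1-Fucci captures (filled circles). CDK1, TOP2A and UBE2C were lowest in G1, whereas CCNB1, PLK1 and CDC20 were lowest in S and high in G1.

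**Figure D2:**
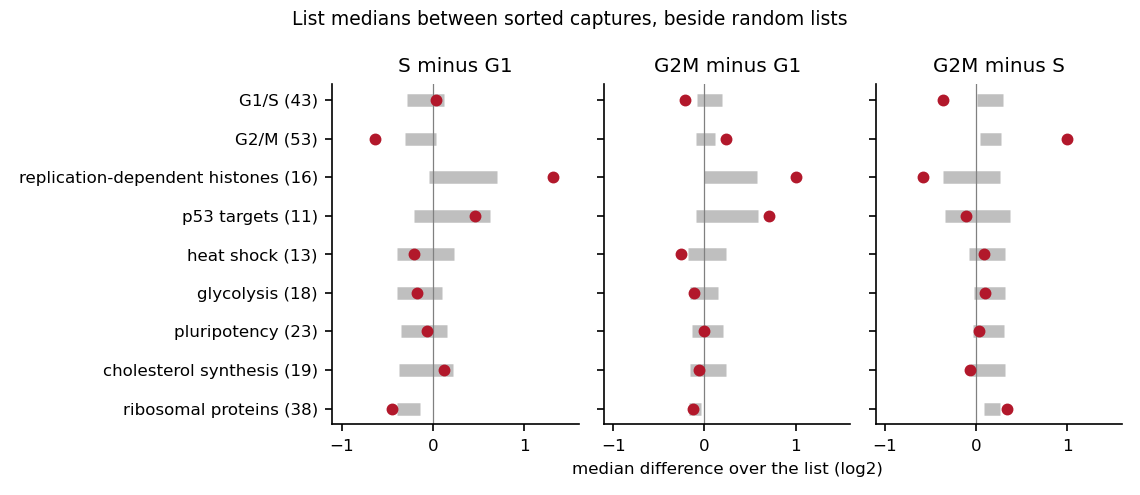
Median log2 difference of each gene list between sorted captures (points, number of measured members in brackets) and the central 95% of 10000 random lists matched on expression (bars). The G2/M list lay below random lists for S less G1 (-0.63) and above them for G2M less S (1.00), and the histones lay above them for S less G1 (1.31).

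In unsorted H1 cells, the question was which genes vary from cell to cell together with mitotic genes. With the G2/M list, 41 of its 53 members and 82 other genes correlated positively (1.14% of 10758 genes tested) and 32 genes negatively (0.297%; limma over the 3 experiments, adjusted p threshold 0.05). KPNA2, an importin, had a mean Spearman correlation of 0.689 ± 0.129 (SD, n = 3), CCNB1 of 0.654 ± 0.0902 and PLK1 of 0.626 ± 0.0161. The spindle checkpoint gene BUB3 (0.597), DEPDC1 (0.588), TRIM59 (0.588), the calmodulin gene CALM2 (0.547), ARHGAP11A (0.527), the cohesin protector SGOL2 (0.523), the kinesin KIF14 (0.502), the midzone protein gene PRC1 (0.496) and ZNF165 (0.471) followed. Histones went the other way, with 8 of 16 members negative (14 adjusted over the list alone), such as HIST1H1B at -0.551 and HIST1H1E at -0.501.

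Of the list's own 53 members, 41 were positive (50 adjusted over the list alone), with CKS2 at 0.705, AURKA at 0.647, UBE2C at 0.618, TOP2A at 0.599, KIF23 at 0.583 and CENPF at 0.582. Replication genes were negative in 11 of 43 members (13 adjusted over the list alone). Of 29 cyclins and regulators 6 were positive (7 positive and 1 negative adjusted over the list alone). CDK1, among the positive cyclins and regulators, is also on the G2/M list. Of 13 heat shock genes 2 were positive (4 adjusted over the list alone), and 1 of 3 ectoderm genes and 1 of 8 immediate early genes were positive (1 and 1 adjusted over the list alone). The pluripotency, glycolysis, cholesterol synthesis, ribosomal protein, p53 target, fibroblast, mesendoderm, definitive endoderm and trophoblast lists gave 0 genes past the threshold, and 0 when adjusted over the list alone, while 1320 of all genes had an unadjusted limma p under 0.05. CCNA2 (0.0903), POU5F1 (0.0278), NANOG (0.184) and SOX2 (-0.0417) were not called. The adjusted p was 5.80e-09 for KPNA2 and 3.61e-09 for CCNB1, with the same sign in each of the 3 experiments. When the list score was shuffled over cells 20 times, 0 genes were called. Without H1 experiment 1, 61 genes were positive and 12 negative, and with no adjustment for genes detected 1.93% of the genes were positive.

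With the G1/S list, 26 of its 43 members and 87 other genes correlated positively in unsorted H1 cells (1.1% of 10758 genes tested), and 87 genes negatively (0.809%). The replicative helicase gene MCM7 (0.401 ± 0.0496, SD, n = 3), the thymidine kinase gene TK1 (0.357 ± 0.149) and the replication factor MCM10 (0.335 ± 0.225) were positive, as were H3F3B (0.347), the splicing factor genes SRSF10 (0.344) and SF3A3 (0.337), the mitochondrial chaperone gene HSPD1 (0.343), GGCT (0.321), the nucleolar genes NPM1 (0.316) and NOLC1 (0.305), RAD54L (0.315) and SYNCRIP (0.311). Mitotic genes were negative in 21 of 53 G2/M members (35 negative and 1 positive adjusted over the list alone), led by CKS2 (-0.495), CENPF (-0.467) and CENPE (-0.431). Histones were positive in 6 of 16 members (9 adjusted over the list alone).

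Of the list's own 43 members, 26 were positive (39 adjusted over the list alone), with CDC6 at 0.507, DTL at 0.506, UHRF1 at 0.469, FEN1 at 0.458, PCNA at 0.454 and WDR76 at 0.439, and with CCNE2 at 0.325 and GMNN at 0.328. Cyclins and regulators gave 3 positive and 3 negative genes (4 and 4 adjusted over the list alone), heat shock genes 2 positive (5 adjusted over the list alone) and ectoderm genes 1 negative (1 adjusted over the list alone). CCNE2 and GMNN, among the positive cyclins and regulators, are also on the G1/S list. Glycolysis gave 0 over all genes and 5 positive adjusted over the list alone, and the trophoblast list 0 and 1 negative. The pluripotency, ribosomal protein, cholesterol synthesis, p53 target, immediate early, fibroblast, mesendoderm and definitive endoderm lists gave 0 by either count, while 1430 of all genes had an unadjusted limma p under 0.05. Between the scores, 38 genes were positive for G2/M and negative for G1/S, 17 were the reverse, and 0 had the same sign in both. CCNB1 was such a gene, with -0.326 for the G1/S list (adjusted p 0.000869). The counts depended on each experiment, with 43 positive and 39 negative genes without experiment 1, 27 and 33 without experiment 2, and 74 and 43 without experiment 3. Without the 6 cells under 1000000 expected counts, an alternative chosen after seeing the depths, 67 were positive and 54 negative, and Pearson correlation gave 54 positive.

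**Figure D3:**
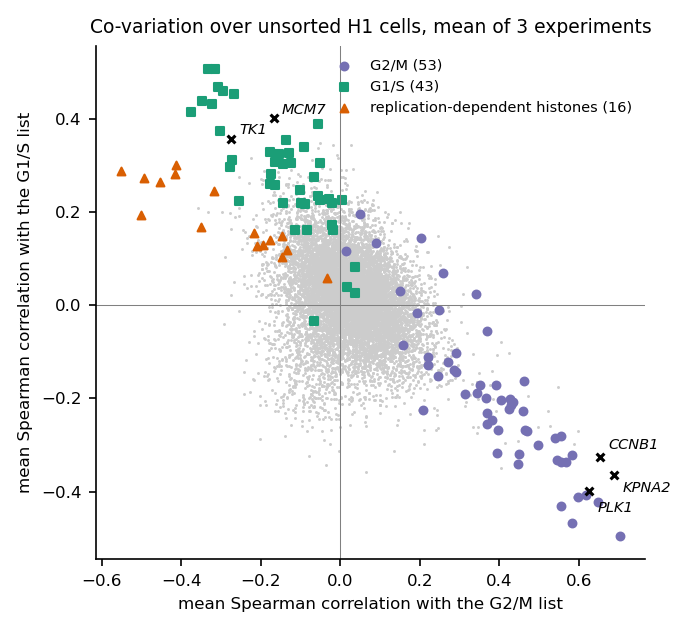
Mean Spearman correlation of each gene with the G2/M list (horizontal) and with the G1/S list (vertical) over unsorted H1 cells, averaged over 3 experiments, with list members coloured and 5 genes outside the lists marked by crosses. G2/M members lie at the lower right and histones at the upper left, as for CKS2 (0.705 and -0.495).

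The genes found in unsorted cells were then compared between the sorted captures. Of the 82 genes outside the list that varied with the G2/M score, 57 (69.5%, 95% Clopper-Pearson interval 58.4% to 79.2%) were higher in G2M than in G1, against a median of 59.8% in random gene sets matched on expression (percentile 97.5). This share depended on the setting. It fell to 62.2% with the log2 of the mean value and to 62.3% without H1 experiment 2. It rose to 76.2% with no adjustment for genes detected, and rose also with cells rescaled to the same total. The random median of 59.8% belongs to the main setting, whose interval includes it. Against S, 78 of the 82 (95.1%) were higher in G2M, with 59.8% in random sets (percentile 100); this difference was chosen after its values were seen. Of the 87 genes outside the list that varied with the G1/S score, 32 (36.8%, interval 26.7% to 47.8%) were higher in S than in G1, against 41.4% in random sets (percentile 14.6). By differences chosen after their values were seen, 33 of them (37.9%) were higher in G2M than in G1, against 49.4% (percentile 0.905), and 48 (55.2%) higher in G2M than in S, against 65.5% (percentile 1.8). The share higher in S than in G1 was 48.8% when each cell was rescaled to the same total. Genes are not independent replicates, so the intervals cover sampling of genes only.

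Within lists, mitotic genes varied together more than replication genes did: the mean pairwise correlation was 0.175 ± 0.0403 (SD, n = 3) for the G2/M list and 0.0987 ± 0.00112 for the G1/S list, and the difference was not tested. Random lists had means of 0.0199 and 0.0167, and none exceeded 0.0822 and 0.0748 in any experiment. Histones had a mean of 0.243 ± 0.0385. Between lists, the mean correlation was -0.0612 ± 0.0285 for G2/M with G1/S, -0.135 ± 0.0338 for G2/M with histones and 0.0656 ± 0.0189 for G1/S with histones.

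A search for pairs of genes that fit a sine pattern over the 213 unsorted cells placed mitotic genes among its top genes. Of 2666 genes searched, the top 5% were taken, and 17 of them (12.7%) belonged to the G2/M or G1/S lists, against 2.25% of the genes searched (Fisher's exact test, p = 1.87e-09, for these cells only). A group of 19 genes held 10 of the list genes (exact p = 1.21e-12), namely AURKA, CDK1, CENPE, CENPF, HJURP, KIF23, MKI67, NUSAP1, TOP2A and UBE2C, together with KPNA2, PAFAH1B2, BUB3, CALM2, PRC1, ARHGAP11A, ACBD3, FAM83D and KIF20A. Another group of 12 genes held 5 of them (exact p = 3.43e-06), namely CDC20, DLGAP5, G2E3, NCAPD2 and TPX2, with CCNB1, PLK1, KLHL24, HIST1H4C, TRIM59, ZFAND5 and DEPDC1. The glycolytic genes ENO1, GAPDH, TPI1 and ALDOA shared a group of 8 with the tubulin genes TUBA1B and TUBB, the actin gene ACTG1 and ATP5B. A group of 7 consisted of near-identical MTRNR2L copies, whose reads cannot be assigned with certainty. Of the G1/S list, 1 gene (USP1) was among the top genes. The best pairs in the groups of 19 and 12 had a median absolute cosine of the phase shift of 0.625 and 0.65. For TOP2A with CDK1 it was 0.85, and for the MTRNR2L copies MTRNR2L1 and MTRNR2L10 it was 1. A pair at a cosine of 1 lies on a straight line, so plain correlation scores well too. The search thus did not separate oscillation from co-variation. The exact p-values of groups were not adjusted over the 9 groups. The 9 groups were poorly separated (mean silhouette 0.0398), and with values rescaled between the 1% and 99% quantiles 7 list genes were among the top genes (exact p = 0.0288), 6 of them in the group with most. Without experiment 3, 11 list genes were among the top genes.

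H1-Fucci cells, compared with unsorted H1 cells, were nearly without transcripts of DNAJC15, a mitochondrial co-chaperone, were lower in PKIB, an inhibitor of protein kinase A, and were higher in GMNN, the inhibitor of replication licensing. DNAJC15 had a mean value of 0.717 ± 0.709 (SD, n = 3 captures) in H1-Fucci and 89.2 ± 11.2 (SD, n = 3) in H1, a log2 difference of -3.98 ± 0.32 (SE; limma adjusted p 7.73e-08). PKIB had capture means of log2(value + 1) of 0.46 ± 0.23 and 3.94 ± 0.30 (SD, n = 3 and 3), a log2 difference of -3.48 ± 0.32 (adjusted p 4.51e-07), with a mean value of 7.68 ± 3.88 left in H1-Fucci. GMNN had log2 means of 10.53 ± 0.20 and 9.11 ± 0.11 (SD, n = 3 and 3), a log2 difference of 1.42 ± 0.19 (adjusted p 0.000328), and each H1-Fucci capture was above each H1 experiment; it lost its call in 2 of 15 settings, without the filter on low values and without trend in limma (adjusted p 0.112). CDT1 differed by 0.38 (adjusted p 0.940).

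In all, 5 genes were higher and 8 lower of 10771 tested. The other higher genes were the metallothionein MT1G (2.90), the matricellular gene CTGF (2.30), RGS5, a regulator of G-protein signalling (1.94), and SIPA1L2 (1.85), with adjusted p from 0.00328 to 0.0160. The other lower genes were SUCLG2, a subunit of succinyl-CoA ligase (-2.26), the cardiac troponin gene TNNI3 (-1.98), the transcription factor gene TFCP2 (-1.95), IGDCC4 (-1.94), ZNF512 (-1.86) and KIAA1324L (-1.82), with adjusted p from 0.000890 to 0.0223. Of these, IGDCC4 lost its call in 10 of 15 settings, TFCP2 in 8 of 15, CTGF in 7 of 15 and SIPA1L2 in 6 of 14. MT1G and ZNF512 each lost it in 5 of 15, RGS5 in 4 of 15, TNNI3 in 4 of 14, KIAA1324L in 3 of 14 and SUCLG2 in 1 of 15. Groups did not overlap in 1213 genes (11.3%), where chance gives 10%, and 669 genes had an unadjusted p under 0.05. Cholesterol synthesis genes had a median of 0.50 (percentile 100), with 17 of 19 members above 0, against an SD of the list median of 0.63 over the H1 experiments; 0 passed over all genes and 3 when adjusted over the list alone, namely INSIG1 (1.6, p 0.0147), SQLE (1.1, p 0.0230) and IDI1 (0.97, p 0.0194), each adjusted over the list alone. Ribosomal proteins had a median of -0.13, with 0 of 38 members above 0 (percentile 0.02) and 0 past either threshold, inside the SD of 0.27 of the list median over the H1 experiments. GMNN was the call in the G1/S list (median 0.13; 1 adjusted over the list alone) and in the cyclins and regulators (median 0.22; 1 adjusted over the list alone), and AFP (1.1) was the call of the definitive endoderm list when adjusted over the list alone (0 over all genes). In the G2/M (median 0.08), histone (0.15), pluripotency (0.06), ectoderm (0.05), mesendoderm (0.57), trophoblast (0.41), fibroblast (0.04), p53 target (0.28), immediate early (0.20), heat shock (0.05) and glycolysis (-0.03) lists 0 genes passed by either count, beside 669 unadjusted over all genes, and the median over all genes was 0.13. Line, passage, sorting and capture go together in this comparison. Each H1-Fucci capture was also a different phase, so the SD over these captures holds phase differences. On the log2 scale it was 1.83 for CDK1 and 0.97 for CCNB1. Genes that change with phase could thus hardly be called, and 0 calls in the G2/M and histone lists do not show equal lines. The mean over these captures weights the phases equally, which need not match the mix in unsorted H1 cells. The 3 H1-Fucci captures are all experiment 1, and if they came from 1 culture they are not independent and the p-values and SEs are too small. PKIB kept its call under each alternative and each left-out capture, and DNAJC15 in the 14 of 15 settings that tested it (its mean was under 50), whereas the counts moved to 2 higher and 4 lower without H1 experiment 2, to 1 and 4 without the S capture, to 12 higher without H1 experiment 1, to 15 higher without the G1 capture and to 5 lower without the G2M capture.

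**Figure D4:**
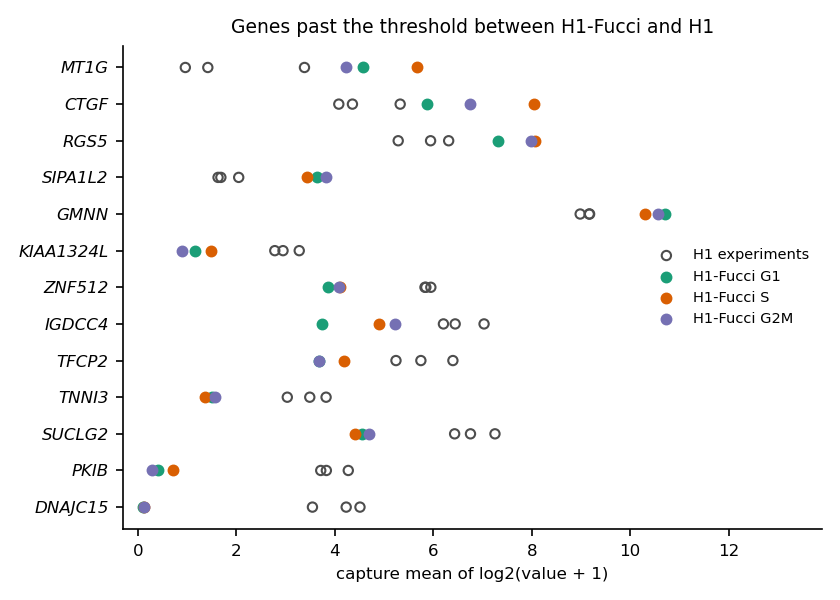
Capture means of log2(value + 1) for the 13 genes past the threshold, in 3 unsorted H1 experiments (open circles) and 3 sorted H1-Fucci captures (filled circles). DNAJC15 lay near 0 in each H1-Fucci capture and between 3.54 and 4.51 in the H1 experiments.

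The 3 H1 experiments differed from one another as well. The median gene had a range of 0.58 and an SD of 0.31 on the log2 scale over the 3 capture means, and 1901 of 10771 genes (17.6%) had a range over 1. CDK1 ranged over 1.5 and CCNE2 over 1.43, CCNA2 over 0.95 and SOX2 over 1.00, whereas CCNB1 ranged over 0.12 and CCND1 over 0.07.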

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

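The omission of the 6 cells under 1000000 expected counts and holding the cell number were chosen after seeing the data. For the G2/M list, 1.93% of the genes tested were positive with no adjustment for genes detected (main 1.14%), and 0.474% were negative with cells rescaled to the same total and 0.252% with a mean of at least 50 (main 0.297%); leaving out an experiment gave 0.567% to 1.45% positive and 0.112% to 0.363% negative. For the G1/S list, positive genes (main 1.1%) were 0.502% with Pearson correlation, 0.576% without 5% of cells at each end and 0.623% without cells under 1000000 expected counts, and negative genes (main 0.809%) were 0.699% with a mean of at least 50, 0.446% without 5% of cells at each end and 0.502% without cells under 1000000; leaving out an experiment gave 0.251% to 0.688% positive and 0.307% to 0.400% negative. The share of G1/S genes higher in S was 48.8% with cells rescaled (main 36.8%). The mean correlation within the G1/S list moved beyond its small SD, to 0.0970 with no adjustment, 0.103 with Pearson correlation, 0.0970 with cells rescaled, 0.0899 without 5% of cells at each end, 0.0882 without cells under 1000000 expected counts and 0.10 with cell number held. The sine search gave 11 list genes among the top genes at the top 2.5% and 7 at the 1% and 99% quantiles (main 17), with 6 in the group with most (main 10); leaving out an experiment gave 11 to 17, and 9 to 11 in that group. Genes higher in H1-Fucci (main 5) were 2 with the log2 of the mean value, 0 without the filter, 3 with a mean of at least 50 and 1 without trend, and genes lower (main 8) were 3, 3 and 3 in the first 3 of these settings; leaving out a capture gave 1 to 15 higher and 4 to 8 lower, with limma pooling the spread. Of the 13 genes called there, 2 (DNAJC15 and PKIB) kept their call in each setting that tested them, which for DNAJC15 were 14 of 15, and 11 lost it in at least 1. The histone median was, for S less G1 (main 1.31), 1.97 at pseudocount 0.1, 0.70 at pseudocount 10 and 0.58 without the filter, and for G2M less G1 (main 1.0) 1.56, 0.42 and 0.37, and 0.37 with the log2 of the mean value. That setting gave a G2/M median of 0.68 for G2M less S (main 1.00) and reversed the G1/S median for S less G1 (-0.0077), the ectoderm (-0.25), MAP2 (-0.25), glycolysis (-0.13) and CCND1 (-0.20) values for G2M less S, and ALDOC (-0.32), ENO2 (-0.26) and S100A4 (-0.022) for G2M less G1. Without the filter the ectoderm median reversed to -0.065 (S less G1) and -0.033 (G2M less G1), and the immediate early median to 0.24 (S less G1). The p53 target median for G2M less S reversed to 0.017 at pseudocount 0.1 and to 0.018 without 5% of cells at each end. Of 1914 comparisons of named phase differences and list medians with their alternatives, 1472 stayed within the SD of the H1 experiments, 429 moved further and 13 reversed; another 21 changed sign, as the cholesterol median did, but from values inside the spread of the H1 experiments, and were not counted as reversed, whereas each change of sign of a G1/S, G2/M or histone median was. Of 962 comparisons of named correlations, 27 lost a call, and these belonged to 20 genes. The 962 include named genes without a call in the main setting, which had none to lose. Apart from the effect of fewer genes or cells tested, the cause was not tested. No paired analysis was possible because each sorted phase has 1 capture and the groups share experiment number 1 alone. Depth limits lowly expressed genes most: 6 H1 cells lay under 1000000 expected counts, and 3 of them were in experiment 1.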

Other observations

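The tests of the mitotic genes in G1, of depth in the drift and of phases for GMNN were chosen after the result was seen. In the pluripotency list, whose median for S less G1 was -0.07 (percentile 59.2), LEFTY1, a secreted inhibitor of NODAL, differed by 2.00 for S less G1 and by -1.52 for G2M less S (H1 range 0.57), NODAL by 1.25 and -0.56 (0.31), LEFTY2 by 0.79 and -0.75 (0.47), and GDF3 by -0.19 and -0.36 (2.23). LEFTY1 had mean values of 0.65 in G1, 28.4 in S and 7.77 in G2M, and LEFTY2 of 6.59, 13.4 and 4.81. The differences of LEFTY1 and LEFTY2 thus rest on low values. Of 11 p53 targets, 9 were higher in G2M than in G1 (median 0.71, percentile 99.6), including ZMAT3 (0.92), RRM2B (0.84), the apoptosis gene BAX (0.82) and MDM2, the ligase that degrades p53 (0.78), and their medians were 0.46 (percentile 86.1) for S less G1 and -0.11 (percentile 21.6; 0.017 at a pseudocount of 0.1) for G2M less S. Of the immediate early genes, FOS differed between G2M and G1 by 2.1 (H1 range 1.34), EGR1 by 1.39 and KLF6 by 1.22, both inside their H1 ranges of 1.90 and 1.64, and MYC by -0.59, inside its range of 0.67, with list medians of -0.23 (percentile 3.48; 0.24 without the filter), 0.63 (percentile 94) and 0.20 (percentile 78.8) for S less G1, G2M less G1 and G2M less S. Ribosomal proteins were lower in S than in G1 in 38 of 38 members (-0.44, percentile 0.08; G2M less G1 -0.12, percentile 35.0; G2M less S 0.34, percentile 99.96), against an SD of 0.27 over the H1 experiments. None of these differences has a replicate.

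In the order S less G1, G2M less G1 and G2M less S, heat shock genes had medians of -0.21 (percentile 26), -0.26 (percentile 0.07) and 0.09 (percentile 36.5), with the chaperone gene HSPA8 at -0.93, -0.70 and 0.23, inside its H1 range of 0.93. Glycolysis genes had medians of -0.17 (percentile 49.6), -0.11 (percentile 15.3) and 0.09 (percentile 23.3; -0.13 with the log2 of the mean value), with LDHA, the lactate dehydrogenase gene, at -0.72 for S less G1 and PFKM, a phosphofructokinase gene, at -1.14 for G2M less G1. Cholesterol synthesis genes had medians of 0.13 (percentile 93.2; -0.04 at a pseudocount of 0.1), -0.06 (percentile 23.4) and -0.07 (percentile 2.00), with MVD, an enzyme of the mevalonate pathway, at 1.42 for S less G1 and -1.56 for G2M less S (H1 range 1.48). The SD of the list median over the H1 experiments was 0.13 for heat shock, 0.05 for glycolysis and 0.63 for cholesterol synthesis. Each cholesterol median lay inside that SD, a spread that percentiles among random lists do not measure. Markers of other cell types were few: ectoderm (3 genes) 0.46, 0.76 and 0.75 (each reversed by an alternative, to -0.065 and -0.033 without the filter and to -0.25 for G2M less S with the log2 of the mean value), fibroblast (5 genes) 0.41, 0.59 and -0.10, BMP4 -0.86, 0.42 and 1.28 (H1 range 1.17), AFP and KRT19 together -0.12, 0.35 and 0.47, and TFAP2C -0.93, -0.30 and 0.62.

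Mitotic genes were high in cells sorted as G1, where 44 of the 52 G2/M members other than CDK1 had a higher mean value than in S. CDK1 allowed at most 15.9% of G2/M cells sorted into G1, if they carry CDK1 as the G2M capture does. The 44 members lay at a median of 6.06 times the level that this share alone would bring. Over the 52 members the median was 6.04 times, with UBE2C at 1.30 and TOP2A at 1.77 times, near that level. CCNB1, of the cyclins and regulators list, lay at 8.46 times. This share alone thus did not account for the G1 level of most members. The ratio allowed for no expression of these genes in G1 cells themselves, and genes equal in G1 and G2M would give a similar ratio. It therefore cannot decide whether such cells raised G1 above S. Exchanged G1 and G2M labels were argued against, because the G2/M median was higher in G2M by 0.23, above random lists, and CCNE1 and CCNE2 were higher in G1, although that median was 0.06 with the log2 of the mean value. Members that peak at different times remain a candidate explanation that could not be decided. Split at the median of their G1 less G2M difference, they correlated more within than between groups in H1 by 0.0279 (random splits at most 0.0144 in 97.5%). The upper group, with CDC20 (0.77) and CCNB2 (0.72), correlated within itself by 0.161, no more than between groups (0.161). The lower group, with CDK1 (-3.59) and UBE2C (-2.82), correlated within itself by 0.216. Transcripts carried over from mitosis into early G1 may also play a part, which was not tested.

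A drift with the cell number in the sample titles was seen in each capture: with genes detected held, 495 of 10771 genes (4.6%) drifted by limma over the 6 captures, 33 higher and 462 lower with number, and 20 shuffles called at most 1 gene. RPL13 had a mean correlation of -0.619 ± 0.0892 (SD, n = 6), HNRNPH1 of -0.562, IMP3 of -0.547 and EIF3F of -0.519, each negative in 6 of 6 captures. The ribosomal protein list did not follow RPL13: its median correlation was 0.0898, with 4 members higher and 3 lower (12 and 3 adjusted over the list alone). In the sine search, 28 of the top genes (20.9%) drifted, 16 of them in the group of 46. In a group of 16 genes, which held the G2/M member ANP32E, 7 drifted. In the groups of 19 and 12, which held most of the mitotic genes, 1 and 1 drifted. Genes detected and depth were argued against as the cause, since 607 genes drifted with both held and 615 with neither, and so was the cell cycle, since 1.62% of drifting genes were called for either list against 2.82% of all genes. Lanes of 24 consecutive numbers could not be excluded, because the drift inside such blocks passed its shuffles in 2 of 6 captures, and what the number stands for is not given in the sources used here.

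GMNN was higher in H1-Fucci than in H1. A different mix of phases in the 2 lines was argued against, because GMNN was above the highest H1 experiment (9.18) in 3 of 3 sorted captures, of which the lowest was 10.31. Reads from a reporter that carries part of the gene may explain it, and could not be told apart from higher expression: GMNN ranked below the lowest H1 rank by correlation with the G1/S list in 0 of 3 H1-Fucci captures, but its rank varied between 10 and 42 over the H1 experiments. For the count of genes between H1-Fucci and H1, the real split of the 6 captures gave 13 genes and the highest of the other splits 4; with 10 splits the share cannot fall under 0.05.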
